A study of Drosophila melanogaster with 2 samples.

How the data were processed

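Whole Drosophila melanogaster embryos of 0 to 24 hours, from flies that carry a CG11085-eGFP fusion, were used for chromatin immunoprecipitation with an antibody against GFP, per the labels. Chromatin was broken by sonication to a size range of 200 to 800 bp, per the labels, and the 2 samples are labelled as biological replicates of 1 group. The labels name a possible control experiment and the deposited file lists name a control file, but no control library was analysed here, so background at the same sites in flies without the fusion cannot be given. The group and the replicate number of each sample were taken from its label.

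The authors deposited 8 peak files in dm6 coordinates, per the file headers and labels, and these were the only measurements used. They comprise a conservative and a larger IDR-thresholded list over both replicates, 1 thresholded list per replicate, and the ranked regions behind each of these lists. The irreproducible discovery rate (IDR) measures how alike 2 sets of regions rank. Peaks were thresholded by IDR and derived from replicate or pooled read sets against 1 control file, per the deposited file lists. The aligner, the peak caller and their versions are not given in the sources used here. The signal of each peak is the value the authors deposited, never negative and on a scale that is not stated, and the signals of the series-level lists come from pooled reads. The IDR score of each peak, a whole number up to 1000, is also the authors' value. The ranked files also hold the −log10 of the global IDR as the authors deposited it, and the signal of each region in both sets compared. The lowest score in all 4 thresholded lists was 830, which stands for a global IDR of 0.01. One of the series-level ranked files was taken as the comparison of the replicates because 83121 of its input regions were identical to regions of replicate 1 and 61695 to regions of replicate 2, while the other had 0 and 0. Each conservative peak was matched to its row there to obtain both replicate signals.

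Read depth is unknown, since the peak files give no read totals. Intervals on shares of peaks therefore cover counting error over peaks only, and the shares in the lists of the single replicates show the spread between replicates.

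Peaks on the arms X, 2L, 2R, 3L, 3R and 4 were compared with ranked regions on the same arms that scored below the list's lowest score, 139970 of them for the conservative list. Genes and TSSs came from Ensembl release 115, which uses the same assembly, and sequence and soft-masking from the NCBI RefSeq copy of that assembly. Entries for transposable elements in the annotation were not counted as genes, which left 18164 genes, 13945 of them protein-coding. Each summit was given 1 class, in the order promoter (within 500 bp of any TSS), 5' UTR or coding exon, 3' UTR, intron or non-coding exon, and intergenic. Shares were compared with Fisher's exact test, two-sided, with conditional odds ratios and 95% intervals, and shares have 95% Wilson intervals. Overlap between replicates counted peaks sharing at least 1 bp, against 1000 random placements within each arm. The signal of promoter peaks was compared with that of other peaks by the difference of medians and 100000 permutations.

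A gene counted as bound when a conservative summit lay within 1 kb of one of its TSSs. The 30 gene lists were fixed by symbol, and each was compared with all other protein-coding genes, with Benjamini-Hochberg adjustment over the 30 lists. For 6 listed symbols the current name was used, and 1 symbol, tal, had no match and was left out. The 27 sequence words were looked for on both strands within 50 bp of the summit and in windows of the same size 250 bp to each side. The test was an exact McNemar test of the summit against 1 flank per peak drawn at random, with Benjamini-Hochberg adjustment over the 27 words, while printed flank shares of these words are means over both flanks. The ratio of each word was also ranked among up to 200 other orderings of its bases. All 2080 words of 6 bases were tested in the same way with Bonferroni adjustment, and their flank shares come from the drawn flank.

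The genes named in the text followed a rule. They were CG11085, the gene of any biotype with the TSS nearest to each of the 15 conservative peaks of highest signal, up to 4 bound members of each list with the highest signal, and the 5 protein-coding genes with most conservative summits by nearest TSS. The rule, the groups, the tests, the lists, the words and most alternative settings were set before the data were examined. Alternatives were the larger IDR-thresholded list, each replicate's own list in place of the conservative list, other windows, other backgrounds and subsets of peaks. A stricter list at a global IDR of 0.01, chosen among them, removed 0 peaks, since that is the authors' own threshold. After seeing the data, a global IDR of 0.001, the removal of peaks that share a replicate's region with a stronger peak and, for the promoter share, the strongest regions that did not pass as background were added.

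The procedures were tested on simulated data. With an odds ratio of 4 planted on the 92 ribosomal protein genes, the list test called them in 100 of 100 runs. The same odds ratio on the 22 chromatin genes was called in 61 of 100 runs, and an odds ratio of 8 on the 17 EGFR pathway genes in 89. Lists with no planted change were called 9 times in 2300 tests. Bound genes were drawn independently in these runs, so neighbouring genes that share a peak were not simulated. TAATTG written into 5% of 2610 summit windows of shuffled bases was called in 20 of 20 runs, and in 2% of windows in 2 of 20. Bases of summits and flanks were pooled for these runs. False calls that the higher A and T content of real summits can give were therefore not measured. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.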

Results

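Chromatin immunoprecipitation followed by sequencing was used to map where the product of CG11085, a homeobox-class gene of Drosophila melanogaster, associated with the genome in whole embryos. The embryos, collected from 0 to 24 hours of development, came from transgenic flies in which CG11085 is fused to enhanced green fluorescent protein (eGFP), and the fusion protein was precipitated with an antibody against GFP. A homeobox encodes a homeodomain, a DNA-binding domain found in many regulators of development. The series holds 1 group of 2 biological replicates, so the questions the design allows are how far the replicates recovered the same sites, where in the genome those sites lie, and which genes and sequence words they carry. The conservative list, which the authors derived from both replicates, held 2649 peaks, of which 2610 lay on the 6 chromosome arms X, 2L, 2R, 3L, 3R and 4. The lists thresholded within each replicate held 2026 peaks in replicate 1 and 1803 in replicate 2. The depth of each library is unknown because the peak files give no read totals. With only 2 replicates, every statement below is limited to the spread between that pair.

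Most sites found in one replicate were found in the other. On the arms, 1294 of the 1750 peaks of replicate 2 (73.9%) overlapped a peak of replicate 1 by at least 1 bp, and 1319 of the 2006 peaks of replicate 1 (65.8%) overlapped a peak of replicate 2. Random placements of the replicate 2 peaks on their own arms gave a mean overlap of 0.799% and at most 1.60% (1000 placements, one-sided permutation p = 0.001, the smallest these placements can give). In the authors' comparison of both replicates, the signal was higher in replicate 1 than in replicate 2 at 2380 of the 2610 conservative peaks, with a median ratio of 1.51 and quartiles of 1.23 and 1.86. Across these peaks the replicate signals correlated with a Spearman rho of 0.710 and a Pearson r of 0.833 on log10 values. Across all 142665 ranked regions on the arms rho was 0.245, and across the 139970 regions that did not pass the authors' threshold it was 0.201. Regions of one genome are not independent replicates, and the threshold itself favours regions that rank alike in both replicates, so no p-value is attached to these correlations.

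**Figure D1:**
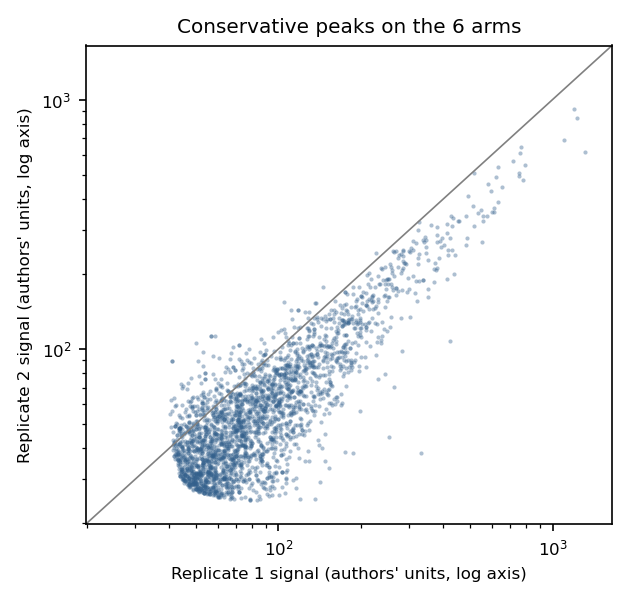
Signal of each of the 2610 conservative peaks on the arms in replicate 1 (x axis) and replicate 2 (y axis), in the authors' signal units on log axes; the grey line marks equal values. Replicate 1 was higher at 2380 peaks.

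CG11085 itself (FBgn0030408) had no conservative peak in or within 1 kb of its gene. The gene lies on chromosome X from 12616316 to 12621216 on the forward strand, with 1 annotated transcription start site (TSS). The strongest of the ranked regions in that stretch, at X 12619727 to 12620066, had a signal of 61.6 and a −log10 global IDR (irreproducible discovery rate) of 0.394, below the lowest value in the conservative list of 2.00. The nearest conservative peak, at X 12629547 to 12629886, had a signal of 165 and its summit 8501 bp beyond the 3' end of the gene and 77 bp upstream of the TSS of Aven. The next ones, at 12631304 to 12631643 and 12632564 to 12632903, had signals of 107 and 106, and the TSS nearest to both summits was that of Tomosyn.

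The strongest sites lay mostly at promoters, led by those of CG14100 and Ugalt. Of the 15 peaks with the highest signal, 11 had a summit within 500 bp of a TSS and 4 lay further inside a gene, and in all 15 replicate 1 had the higher signal. The strongest, at 3L 19590463 to 19590790, had a signal of 2118 (1200.5 in replicate 1 and 921 in replicate 2), and its summit lay 96 bp upstream of the TSS of CG14100. It was followed by a peak at X 2703727 to 2704048, with a signal of 2058 and a summit 41 bp upstream of Ugalt, which encodes a UDP-galactose transporter. The third, at 2L 6612549 to 6612901 with a signal of 1948, lay 1026 bp downstream of the nearest TSS of CG11050, in an intron or non-coding exon. A peak at 2R 15217588 to 15217906, 121 bp upstream of mRpL41, a mitochondrial ribosomal protein gene, had a signal of 1778. Tcs5, a tRNA modification gene, had a signal of 1397 at 3L 5139343 to 5139643, with the summit 102 bp upstream of its TSS. Next came ph-p, a Polycomb group gene, with 1343 at X 2137220 to 2137497, 497 bp upstream of its TSS. CG7601 (1329), CG5611 (1269.9) and Art3 (1251), an arginine methyltransferase gene, had summits 99, 124 and 126 bp upstream of their TSSs. The antisense RNA gene asRNA:CR45928 (signal 1247) and CG8320 (1089) had summits 81 and 87 bp downstream. The transcription factor gene Adf1 (1246), HmgZ (1179), which encodes a high-mobility-group protein, and CG32772 (1126) had theirs in an intron or non-coding exon, 781 bp downstream, 558 bp upstream and 1253 bp downstream of a TSS. Atat, an α-tubulin acetyltransferase gene, completed the 15 with a signal of 1047 and a summit 125 bp upstream. Each of these peaks is named by the nearest TSS only, and some summits also lay within 1 kb of another gene's TSS. This held for eIF2Bbeta at the Ugalt peak, mRpS10 at the Art3 peak and eIF6 at the asRNA:CR45928 peak.

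Peaks concentrated at promoters and were rare in coding sequence. Summits within 500 bp of an annotated TSS made up 55.3% of the conservative peaks (1444 of 2610, 95% Wilson interval 53.4 to 57.2), against 13.2% of the 139970 ranked regions that did not pass. The odds ratio was 8.14 (95% interval 7.51 to 8.81, Fisher's exact test, two-sided). Against the 2610 strongest of them, of which 28.8% lay at promoters, it was 3.06 (95% interval 2.72 to 3.44, Fisher's exact test, two-sided), a background added after the data were seen. The median signal was 69.6 in these regions and 124 in the peaks, so signal was not fully matched. The share was 62.5% in the list of replicate 1 and 57.4% in that of replicate 2. Random placements of the conservative peaks put 13.6% at promoters on average and 15.5% at most (1000 placements, one-sided permutation p = 0.001, the smallest these can give). The 4 other classes were all less frequent in peaks than in the regions that did not pass. All 5 classes passed the test after Benjamini-Hochberg adjustment. Each summit has 1 class, so a larger promoter share by itself lowers the other shares, and these tests are not independent. Of the 1166 peaks outside promoters, introns and non-coding exons held 781, intergenic sequence 299, 5' UTRs and coding exons 61 and 3' UTRs 25. Of the regions that did not pass, these classes held 56436, 36365, 25127 and 3551. Outside promoters, the share of introns and non-coding exons was thus higher in peaks and the other shares lower, which was not tested. Introns and non-coding exons outside promoters held 29.9% of all peaks against 40.3% of all regions that did not pass. The shares were 11.5% against 26% for intergenic sequence, 2.34% against 18% for 5' UTRs and coding exons, and 0.958% against 2.54% for 3' UTRs. In the lists of replicates 1 and 2 the shares were 26% and 29.9% for introns and non-coding exons, 9.07% and 11.03% for intergenic sequence, 1.60% and 0.971% for 5' UTRs and coding exons, and 0.847% and 0.629% for 3' UTRs.

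Promoter summits lay mainly just upstream of the start site. Of the summits within 500 bp of the nearest protein-coding TSS, 1170 lay upstream and 201 at or downstream of it, so that 85.3% were upstream (95% Wilson interval 83.4 to 87.1), with a median position of −100 bp. The upstream share was 81.5% in the list of replicate 1 and 86.9% in that of replicate 2. Among the ranked regions that did not pass, it was 43.6% (odds ratio 7.52, 95% interval 6.44 to 8.80, Fisher's exact test, two-sided p = 3.79e-208); this comparison was added after the data were seen. Another 988 peaks (37.9%) lay over 1 kb from any protein-coding TSS and 199 (7.62%) over 10 kb. Promoter peaks were also stronger, with a median signal of 138 (quartiles 98.8 and 209) against 113 (86.7 and 162) for the other 1166 peaks. The difference of 24.9 passed a two-sided permutation test (p = 1e-05, the smallest that 100000 permutations can give). In the list of replicate 1 the medians were 92.6 and 86.0, a difference of 6.63 (permutation p = 0.00973). In that of replicate 2 they were 67.9 and 61.3, a difference of 6.64 (permutation p = 2e-05). Relative to the medians, both differences were smaller than in the conservative list. At a global IDR of 0.001 or below, a setting added after the data were seen, the difference was 13.6 (medians of 199 and 186, permutation p = 0.0146).

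**Figure D2:**
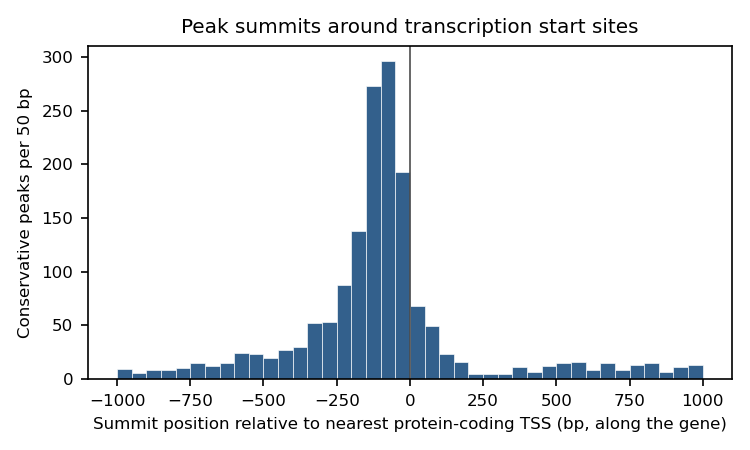
Number of conservative peaks per 50 bp (y axis) by the position of the summit relative to the nearest protein-coding TSS, in bp along the gene (x axis, negative values upstream). Of the summits within 500 bp, 1170 are upstream and 201 at or downstream of the start site.

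Ribosomal protein genes stood out among 30 gene lists fixed for this embryo study. A conservative summit lay within 1 kb of a TSS in 52 of the 92 ribosomal protein genes (56.5%) against 14.8% of the other protein-coding genes (odds ratio 7.45, 95% interval 4.83 to 11.6, Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p = 1.36e-18 over 30 lists). The strongest were RpS27, with a signal of 675 and a summit 2 bp upstream of its TSS at 3R 25247516, RpL7 (557, 26 bp downstream, 2L 10201030), RpL34b (499, 82 bp upstream, 3R 9401308) and RpS28b (425, 40 bp upstream, X 9554583). The RpS27 summit also lay within 1 kb of a TSS of Nup37. The lists of the single replicates reached 56 ribosomal protein genes in replicate 1 and 40 in replicate 2. In all, 2109 of 13945 protein-coding genes (15.1%) had a summit within 1 kb of a TSS.

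Genes of sensory reception and of the cuticle were bound less often than other genes. Among the odorant and gustatory receptor genes 1 of 119 had a peak, Gr64e, with a signal of 84.9 (odds ratio 0.0471, 95% interval 0.00118 to 0.268, Fisher's exact test, adjusted p = 1.62e-06). Among the cuticle protein genes 1 of 118 had one, Cpr73D, with a signal of 116 at a summit 794 bp downstream of its TSS (odds ratio 0.0475, 95% interval 0.00119 to 0.270, Fisher's exact test, adjusted p = 1.74e-06). In the list of replicate 1 no receptor or cuticle gene was bound, and in that of replicate 2 there were 2 receptor genes (odds ratio 0.135, 95% interval 0.0161 to 0.499) and 1 cuticle gene (0.0674, 95% interval 0.00169 to 0.384). The 2610 strongest regions that did not pass reached 3 receptor genes (odds ratio 0.274, 95% interval 0.0557 to 0.824). They reached 6 cuticle genes (0.570, 95% interval 0.204 to 1.28). Neither list was called there after adjustment, but low receptor counts were thus not limited to the peaks. The receptor, cuticle and ribosomal protein lists were called in the same direction in both single-replicate lists. Fisher's exact test treats list members as independent. Many receptor and cuticle genes have serial names, such as Gr22a to Gr22f and Ccp84Aa to Ccp84Ag, and may lie side by side. Their p-values may then be too small.

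No list of patterning or homeobox genes passed the test. None of the 8 Hox genes, the 11 pair-rule genes or the 11 genes of the Hedgehog pathway had a conservative summit within 1 kb of a TSS; the 95% intervals of their odds ratios reached up to 3.29, 2.24 and 2.24. Among the other ANTP-class and NK-type homeobox genes 6 of 32 were bound (odds ratio 1.30), with 5 in the list of replicate 1 (1.21) and 2 in that of replicate 2 (0.530). These included Dll, which acts in limb development, with a signal of 379 at 2R 24814644 to 24814819 (333 in replicate 1 and 38.5 in replicate 2), NK7.1 (232), tin (169), a heart and mesoderm regulator, and ro (99.5). Of the 41 other homeobox genes bcd (168), the anterior determinant, and PHDP (107) were bound. The gap gene list had 1 bound member of 11, cnc (114), the segment polarity list 1 of 14, nkd (199), and the dorsoventral list 1 of 20, again tin. The dorsoventral odds ratio was 0.295, with 1 gene in the list of replicate 1 (0.344) and 3 in that of replicate 2 (1.40).

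Single members were also bound in the lists of tissue differentiation. In the neuroblast list 1 of 27 genes was bound, brat (325), and in the neuronal list 1 of 27, elav (487), an RNA-binding protein gene used as a marker of neurons. The glial list had moody (604) and Gs2 (211) among 13 genes (odds ratio 1.02), with 2 in the list of replicate 1 (1.19) and 4 in that of replicate 2 (3.54). Of 23 mesoderm and muscle regulators 4 were bound, mbc (174), tin, Mef2 (114) and lbl (78.5), and of 20 muscle structural genes sls (184) and Actn (144). The peak of Actn, at X 2041309 to 2041648, was also the one assigned to usp, which lies beside it. The list of endoderm and gut genes had grn (106) among 13 genes, the tracheal and epidermal list trh (151) and shn (101) among 19, the haemocyte list ush (155) among 14, and the germline list bgcn (273) and nanos (121) among 14. With the conservative peaks no list in this paragraph passed the test, with adjusted p between 0.553 and 1 by Fisher's exact test. The glial list passed it in neither single-replicate list.

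Among signalling and chromatin genes, the EGFR and chromatin lists had the highest bound shares, without passing the test. Of 17 genes of the EGFR pathway 5 were bound, led by its ligand gene spi (326), Raf (160), sty (157) and aos (117), an odds ratio of 2.34 (95% interval 0.646 to 7.15, adjusted p = 0.611, Fisher's exact test). Of 22 chromatin, Polycomb or trithorax genes 6 were bound, led by ph-p (1343), the chromatin remodeller gene brm (705), the histone methyltransferase gene E(z) (342) and Trl (241), which encodes GAGA factor. The odds ratio was 2.11 (95% interval 0.675 to 5.68, adjusted p = 0.557, Fisher's exact test). The 2610 strongest regions that did not pass reached 5 EGFR genes (odds ratio 4.46, 95% interval 1.23 to 13.6). They reached 4 chromatin genes (2.38, 95% interval 0.584 to 7.23). Neither list was called there after adjustment, but odds ratios above 1 were thus not limited to the peaks. The Notch list had 4 of 20 genes bound, numb (315), E(spl)m3-HLH (117), Su(H) (114) and E(spl)mdelta-HLH (18.03). Without peaks that share a replicate's region with a stronger peak, 3 of the 20 were bound. The Wnt list had nkd and sgg (199), the BMP list Mad (130) and shn, the axon guidance list PlexA (291), unc-5 (264), Sema1a (106) and Fas2 (68.7) among 25 genes, and the clock and ecdysone list usp (144) and Pdp1 (138). When each summit was assigned to the nearest TSS at any distance, the EGFR list (10 of 17, adjusted p = 2.09e-04), the chromatin list (10 of 22, adjusted p = 0.00279) and the axon guidance list (10 of 25, adjusted p = 0.00778) passed Fisher's exact test as well. With any summit in the gene body or within 5 kb of it, none of these 3 was called against 10000 random lists matched in gene length (EGFR 13 bound against 7.49 on average and chromatin 16 against 9.52, both with adjusted p = 0.0591, axon guidance 15 against 11.7, adjusted p = 0.538, two-sided permutation test).

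Of the remaining lists, 8 of 48 proteasome genes were bound, led by Prosalpha3 (154), Rpn6 (151), Rpn3 (151) and Rpt5 (141), and 3 of 15 heat shock genes, Hsp27 (516), Hsp83 (239.8) and Hsp26 (80.9). The proteasome odds ratio was 1.12, with 6 genes in the list of replicate 1 (0.934) and 4 in that of replicate 2 (0.723). The only bound entry of the chorion list was Cp190 (311), which matched by the spelling of its symbol and encodes an insulator protein, not a chorion protein.

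**Figure D3:**
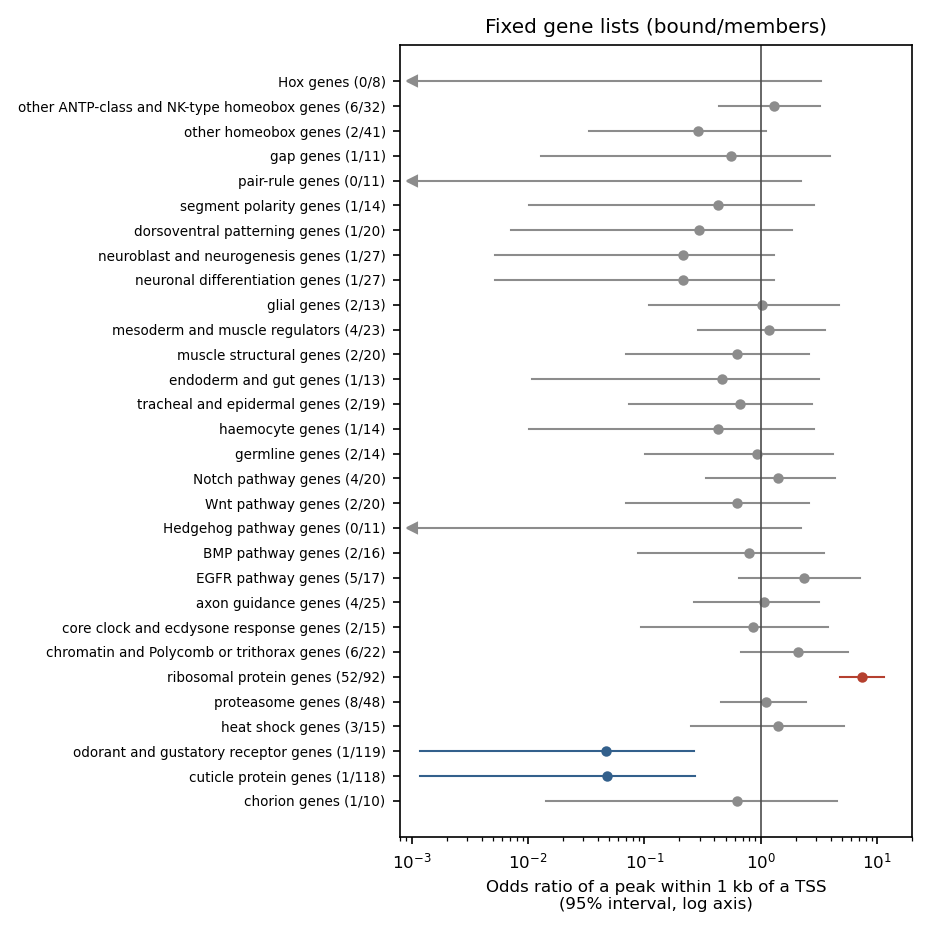
Odds ratio of a conservative summit within 1 kb of a TSS for the members of each of 30 gene lists against the other protein-coding genes (x axis, log scale), with 95% intervals; arrows mark lists with 0 bound members, and red and blue mark lists called higher and lower. Ribosomal protein genes are called higher, and odorant and gustatory receptor genes and cuticle protein genes lower.

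The genes with most peaks were CHES-1-like, CG43245, Tlk, scyl and Hr4. CHES-1-like, a forkhead-type transcription factor gene, was the nearest protein-coding gene to 9 summits, between X 7691665 and 7707006 in its gene body, with signals from 85.8 to 560. CG43245 was the nearest gene to 8 summits spread from 3L 10738715 to 10776785, all over 1 kb from its TSS, with signals from 5.31 to 367. Tlk, a Tousled-like kinase gene, had 7 summits from X 3719831 to 3774472 (signals 76.2 to 889), scyl 7 from 3L 11252322 to 11262329 (72.0 to 166), and Hr4, a nuclear receptor gene, 6 from X 1947744 to 1984329 (88.2 to 224).

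Summits carried BEAF-32-type and replication-element words more often than the sequence beside them. CGATA, the word bound by the insulator protein BEAF-32, occurred within 50 bp of 17.7% of the 2610 summits and in 12.4% of windows centred 250 bp to each side (ratio 1.43, exact McNemar test, two-sided, Benjamini-Hochberg adjusted p = 2.93e-07 over 27 words). The DNA replication element TATCGATA, which contains it, occurred at 2.41% against 0.747% (ratio 3.23, adjusted p = 1.31e-06 by the same exact test). Their ratios exceeded those of 89.8% and 95% of other orderings of the same bases. By the same exact test, at the 1444 promoter peaks CGATA was present at 22.8% of summits against 13.7% of flanks (adjusted p = 1.36e-08) and TATCGATA at 4.16% against 1.21% (adjusted p = 2.21e-06). At the other 1166 peaks the exact test found no difference past the threshold, with shares that were 11.3% against 10.7% (adjusted p = 0.752) and 0.257% against 0.172% (adjusted p = 0.767), and the difference between both sets of peaks was not tested.

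The homeodomain words TAAT, TAATTA and TAATTG were also more frequent at summits, but by less than most other orderings of the same bases. TAAT was present at 74.1% of summits and 56.3% of flanks (ratio 1.32, adjusted p = 6.04e-38), TAATTA at 8.66% and 5.88% (1.47, adjusted p = 1.50e-04) and TAATTG at 11.0% and 8.72% (1.26, adjusted p = 0.00960), by the exact McNemar test. Among 4, 13 and 59 other orderings of the same bases, respectively, these ratios stood at the percentiles 25, 0 and 5.08. The TAATTG call was lost in the list of replicate 1 (ratio 1.05, adjusted p = 0.880) and in the authors' larger IDR-thresholded list (ratio 1.11, adjusted p = 0.167). Summit windows held 64.1% A and T on average (SD 10.8 over 2610 peaks) against 57.0% in the flanks (SD 7.42). The Abd-B or Cad-type word TTTATG (12.5% against 10.04%) and runs of 6 A (25.9% against 19%) were higher as well. The words called lower were the GAGA element GAGAG (10.1% against 15.2%), the NK-2-type word CAAGTG (5.02% against 6.97%), the E-box CANNTG (34.8% against 40.8%), its form CACGTG (0.843% against 1.65%) and the CA repeat CACACA (6.13% against 11.5%). The ratios of GAGAG, CAAGTG, CACGTG and CACACA were ranked among 9, 179, 101 and 19 other orderings of the same bases. They stood at the percentiles 33.3, 24.6, 11.9 and 5.26, and CANNTG was not ranked. The ratio of TTTATG stood at the percentile 27.6. The CACGTG call was lost in the list of replicate 1 (ratio 0.853, adjusted p = 0.769) and in the larger list (0.653, adjusted p = 0.107), by the exact test. The other 15 of the 27 words passed the test in neither direction over all peaks, although within 25 bp of the summit the TALE word TGACAG was called higher (1.92% against 1.21%, ratio 1.59, exact McNemar test, adjusted p = 0.0347). Within 50 bp it was called higher at the promoter peaks (4.02% against 2.08%, ratio 1.93, exact McNemar test, adjusted p = 0.00744), and not at the other peaks (ratio 0.784, adjusted p = 0.631, exact test), and the difference between both sets of peaks was not tested.

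Among all 2080 words of 6 bases, 144 were more frequent at summits and 132 in the flanks (exact McNemar test, Bonferroni-adjusted p under 0.05). The 19 words with the highest z were made of A and T alone, led by AAATAT at 31.0% of summits and 17% of flanks. The leading word with a G or C was CGATAG, at 7.32% against 2.15% (191 and 56 peaks, exact test, adjusted p = 2.89e-15), followed by TCTTAA (9.81% against 4.33%), CTTAAA (13.8% against 7.66%) and ACAGTG (8.62% against 4.02%).

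**Figure D4:**
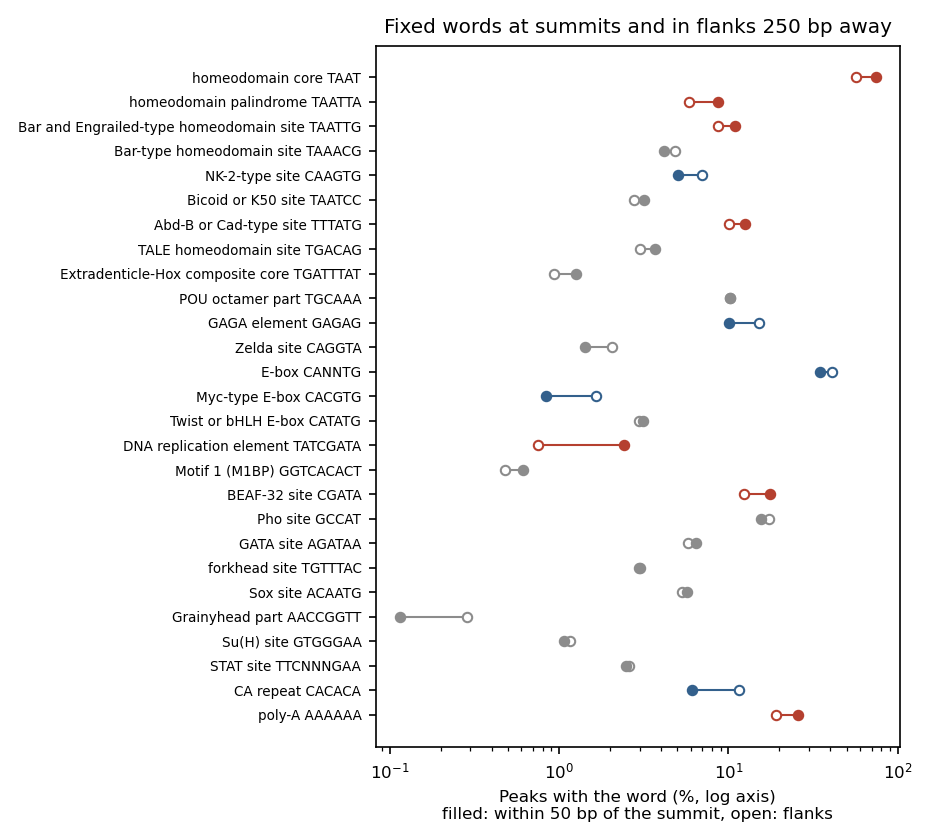
Share of the 2610 conservative peaks with each of 27 fixed words (x axis, percent, log scale) within 50 bp of the summit (filled circles) and in flanking windows 250 bp away (open circles); red and blue mark words called higher and lower at the summit. TATCGATA has the widest gap among those called higher, 2.41% against 0.747%.

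The X chromosome, which carries CG11085, held 504 of the 2610 peaks, 19.3% (95% Wilson interval 17.8 to 20.9), against 18.2% of the regions that did not pass (odds ratio 1.08, 95% interval 0.976 to 1.19, Fisher's exact test, two-sided p = 0.131). The single-replicate lists, each against its own background, passed the exact test, with 19.1% in replicate 1 (odds ratio 1.20, p = 0.00218) and 20.5% in replicate 2 (odds ratio 1.36, p = 6.12e-07). X makes up 17.6% of the length of the arms, and against that share the conservative peaks passed as well (exact binomial test, two-sided p = 0.0221). These X counts leave out 39 further conservative peaks on scaffolds assigned to X. There 39 of 897 ranked regions (4.35%) reached the list's lowest score, against 1.89% on the arms. The X share with these scaffolds included was not tested and could differ from the result above. Chromosome 4 held 1 peak, that of the axon guidance gene PlexA at 1027209 to 1027374.

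Soft-masked sequence, the repeats and low-complexity stretches marked in the reference genome, was more frequent at summits. Over 50% of the bases within 50 bp were masked at 264 of 2610 summits, 10.1% (95% Wilson interval 9.02 to 11.3), against 5.61% of the regions that did not pass (odds ratio 1.89, 95% interval 1.66 to 2.15, Fisher's exact test, two-sided p = 3.59e-19). The share was 9.92% in the list of replicate 1 and 10.7% in that of replicate 2.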

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

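The ranking of words among other orderings was set before the data were examined. Its use in this part as a test of a homeodomain site was decided after the results were seen. The shuffles for CGATA and AAATAT were also chosen after that. The first and the second results below come from data that the comparisons above leave out.

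The conservative list holds 39 peaks outside the 6 arms, all of them on scaffolds assigned to the X chromosome. Of 897 ranked regions on these scaffolds 39 (4.35%) reached the list's lowest score, against 1.89% of the 142665 regions on the arms. The strongest had a signal of 1001 and ranked 19 in the whole list. The replicate lists held 20 peaks outside the arms in replicate 1 and 53 in replicate 2, counted without regard to the type of scaffold.

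Another 133 ranked regions reached the lowest score of the conservative list but are not in it. Of these, 38 lay on unplaced scaffolds and 10 on Y sequences, classes from which the list holds no peak. The other 85 lay on the arms. Among the 85, the 5 strongest, chosen after their values were seen, lay nearest to cbt (signal 1647, 2L 480925 to 481242, which would rank 5 in the list), Lk6 (1054), larp (631), CG18428 (618) and CG6966 (563). The step that removed them is not given in the sources used here beyond the use of a further annotation file.

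The homeodomain words TAAT, TAATTA and TAATTG were more frequent at summits than beside them. This did not hold for all homeodomain-type words. TTTATG was called higher and CAAGTG lower, and TAAACG, TAATCC, TGATTTAT and TGACAG were called in neither direction within 50 bp over all peaks. Either TAATTA or TAATTG was present at 18.7% of summits. In 100 shuffles of the same windows that kept every dinucleotide the share was 20.3% to 24.2%. The summits thus held these words no more often than their own dinucleotide composition gives. The flanks were not shuffled, so whether composition accounts for the excess over the flanks was not measured. The summit-to-flank ratios of both words were at or below the percentile 5.08 among other orderings of their bases. The words thus did not stand out from these orderings. Because this use of the ranking was decided after the results were seen, it is no independent test of a TAATTA or TAATTG site. CGATA went the other way, at 17.7% of summits against 9.58% to 12.3% in the shuffles. AAATAT, made of A and T alone, was at 31.0% against 19.4% to 22.6%, but it was picked as the leading one of 2080 words and no allowance was made for that choice. Binding of CG11085 to these words, to other words or through partners stays open. The design has a single group, and no biological explanation was tested apart from the counts of the fixed words and their orderings.

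Ribosomal protein promoters were bound more often than other promoters. Random lists matched on the number of TSSs had 16.6 bound members on average against 52 (adjusted p = 0.002 by resampling 10000 lists, a permutation test), which argues against TSS number as the cause. Of the 52 bound genes 49 (94.2%, exact 95% interval 84.1 to 98.8) were themselves the gene nearest to a peak. Most of these peaks were thus not closer to the TSS of another gene. But 37 of the 52 had a divergent protein-coding TSS within 1 kb upstream. At such shared promoters the nearest TSS cannot tell which gene a peak belongs to, so peaks of neighbouring genes stay open. Among the 2610 strongest regions that did not pass, the odds ratio of ribosomal protein genes was 1.45 (95% interval 0.696 to 2.75). Signal at active promoters whatever the tagged protein stays open. These regions exclude the peaks, so promoters with reproducible signal of any origin are left out, and this odds ratio cannot decide the question. No library without the fusion was analysed here.

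Some conservative peaks had a signal far below the rest, 101 of 2649 under 20 against a median of 127 for the others, although their median score was 1000. Of these, 100 (99.0%, exact 95% interval 94.6 to 100) shared a replicate's region with a stronger peak of the list, against 1.53% of the others. Their median replicate signals, 66.6 and 41.9, were close to those of the other peaks, 76.2 and 51.7. A candidate explanation is that 1 replicate region was paired with several pooled regions, so that weak neighbours took on the rank of a strong one. The peak of E(spl)mdelta-HLH, with a pooled signal of 18.03 and replicate signals of 74.5 and 44.7, may be such a case. Without peaks that share a replicate's region, the Notch list had 3 bound genes in place of 4.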

How the results depend on the processing

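The added settings here, a global IDR of 0.001, the removal of peaks that share a replicate's region and, for the promoter share, the strongest regions that did not pass as background, were chosen after seeing the data. The promoter share, the 5 classes, the overlap between replicates, the promoter signal difference and the share in repeats kept their direction and their side of the threshold in every setting run for each. The promoter share went from 52.5% with protein-coding TSSs to 66.1% with a 1 kb window. The signal difference was 13.6 at the stricter IDR, against 24.9. The 3 called gene lists were called in the same direction in all 9 other settings. With the nearest TSS at any distance 6 lists were called in place of 3, the EGFR, chromatin and axon guidance lists being added with 10 bound genes each. The X share of 19.3%, counted without the scaffolds assigned to X, passed the test against arm length but not against the regions that did not pass. Nor did it there in the larger list (18.6%, p = 0.347), at the stricter IDR (20%, p = 0.105) or without shared regions (19.5%, p = 0.0924), by Fisher's exact test. The lists without 1 replicate gave 19.1 to 20.5% and passed, each against its own background. Rank agreement rose to a rho of 0.710 over the passing regions alone. Among the words, values here are summit-to-flank ratios. TAATTG lost its call in the larger list (1.11), without shared regions (1.24), in the 100 bp window (1.09) and at mostly unmasked peaks (1.18). CACGTG lost its call in the same settings (0.653, 0.434, 0.711 and 0.611). In the single-replicate lists TAATTG gave 1.05 to 1.17, CACGTG 0.291 to 0.853, CAGGTA 0.605 to 1.09, GGTCACACT 1.06 to 3.45, GCCAT 0.814 to 0.906 and AGATAA 1.11 to 1.49, with calls in 1 of these lists. CAGGTA was also called lower in the larger list (0.667), TGACAG higher in the 25 bp window (1.59), and GGTCACACT (2.43) and AGATAA (1.20) higher in the 100 bp window. Among peaks over 1 kb from a TSS 2 words were called higher in place of 7, with 884 of 2610 peaks left. There TAATTA (1.58), TAATTG (1.17), CAAGTG (0.652), TTTATG (1.09), GAGAG (0.728), CACGTG (0.526), TATCGATA (2) and CGATA (1.16) lost their calls. The cause was not tested for the lists, the X share or the words. Read depth is unknown, so what it limits cannot be given.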

Other observations

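All comparisons in this part were chosen after the data were seen. Gene families defined by symbol were compared in the same way as the fixed lists. Of 60 ionotropic receptor genes 0 had a conservative summit within 1 kb of a TSS (odds ratio up to 0.354, adjusted p = 0.00128), of 51 odorant-binding protein genes 1, Obp99b (odds ratio 0.112, adjusted p = 0.0247), and of 85 cytochrome P450 genes 3, Cyp6u1, Cyp310a1 and Cyp6a14 (odds ratio 0.204, adjusted p = 0.00876; Fisher's exact test with Benjamini-Hochberg adjustment over 15 families). Mitochondrial ribosomal protein genes, led by mRpL41, mRpS10, mRpL23 and mRpS23, had 19 of 73 bound (odds ratio 1.98, 95% interval 1.11 to 3.41, adjusted p = 0.0505 by the exact test), which missed the threshold. The peak of mRpS10 is the one named above for Art3. Mediator subunit genes, led by MED17, had 8 of 25 (odds ratio 2.65, 95% interval 0.987 to 6.48, adjusted p = 0.129 by the exact test). Translation initiation factor genes had 7 of 44 (odds ratio 1.06) and complex I subunit genes 7 of 40 (1.19), neither past the test, and the other 8 families did not pass it either.

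The 8 fixed lists of patterning, homeobox and neuroblast genes held 145 genes together, of which 11 (7.59%) had a summit within 1 kb of a TSS against 15.2% of other genes (odds ratio 0.458, 95% interval 0.223 to 0.848, Fisher's exact test, two-sided p = 0.00982). By the nearest TSS at any distance the direction turned over, with 30 of the 145 bound (20.7%) against 14.3% of other genes (odds ratio 1.56, 95% interval 1.00 to 2.35, Fisher's exact test, two-sided p = 0.0421). With summits in the gene body or within 5 kb, none of the 8 lists was called against length-matched random lists. The neuroblast list had 4 bound against 10.5 on average and the other homeobox genes 10 against 18.2 (both adjusted p = 0.0591, two-sided permutation test). Only the Hox list, with 4 against 3.73, was above its mean. The 145 genes together were not tested in this way.

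Genes with a divergent protein-coding TSS within 1 kb upstream, 5052 in all, were bound in 26.7% of cases against 8.53% of other genes (odds ratio 3.91, 95% interval 3.54 to 4.31). One summit between a pair of such genes counts for both, and with each summit counted only for the gene of the nearest TSS the shares were 14.5% and 8.03% (odds ratio 1.95, 95% interval 1.75 to 2.18).

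The arm 3R held 23% of the peaks against 25.5% of the regions that did not pass (odds ratio 0.871, adjusted p = 0.0192 over 6 arms, Fisher's exact test), and no other arm passed that adjusted test.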
